A study of Rattus norvegicus with 12 samples.

How the data were processed

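Total RNA from renal cortex was labelled with biotin and measured on Affymetrix 3′ expression arrays, 1 array for each of 12 kidney grafts, per the labels' protocols. The labels and the series design name 6 wild-type and 6 MRP2-deficient grafts, all in wild-type recipients, and the groups and replicate numbers were taken from the sample titles. The deposited values are probe set intensities on a linear scale, 1 column per array and 31099 probe sets. MAS5 and GCOS, the software that turns the probes of a set into a signal, are named in the submitters' processing notes, without versions. The deposited intensity values of each array behaved as a signal with 1 decimal divided by a constant of that array, between 104 and 197. With this constant 99.8% to 99.9% of the values of each array were whole multiples of the last decimal, within a tolerance of 0.01 of a step. What the constant was taken from is not given in the sources used here. Low values were set to 0.01 before deposit, which held for 3.56% of all values. Dividing an array by a constant does not change the order of probe sets within it, and a setting of low values to a minimum hides differences between dim probe sets.

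From these values 57 control probe sets were left out of the comparison. Values under the pooled 20th percentile of all values, 0.0694, were raised to it, and log2 was taken, so that a fold change of a gene near this floor is understated. The 18625 probe sets with a mean log2 signal at or above its 40th percentile over the other 31042 probe sets were tested. The median log2 signals of the arrays lay between -0.167 (deficient replicate 14) and 0.0532 (wild-type replicate 6). The arrays were not normalized further, so small differences can hold part of this spread. The fit was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with graft genotype as the sole factor and Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05. Single values per array were compared by exact two-sided permutation tests over all assignments of the 12 arrays into 6 and 6, which cannot give a p below 0.00216.

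Genes were named through the platform annotation, in which 20832 probe sets had 1 gene symbol, 436 had several and were not named, and 9780 probe sets other than controls were not listed. Symbols of 20764 probe sets were updated through their Entrez number to those of the GRCr8 gene table. That table was used for names and gene order alone, since the build behind the array is not given in the sources used here. For gene lists each gene was represented by its probe set with the highest mean, which gave 10639 genes. There were 25 lists, of transporters, conjugation, oxidative and other stress, nephron segments, cell types, injury, matrix, immunity and metabolism. The 24 lists with at least 5 tested genes were compared with all other genes by camera with a preset inter-gene correlation of 0.01 and, as alternatives, with an estimated correlation and by fry, which asks whether the genes of a list move one way on balance. Members that no single-gene probe set named were not analysed here. Of the fry tests, no list passed in the directional form, where the lowest adjusted p was 0.166. In the mixed form, which asks whether members change in either direction, the NRF2 list passed (adjusted p = 0.0133). The glutathione and heat shock lists had an unadjusted mixed p under 0.05 and an adjusted p of 0.277 each. Genes beside Abcc2 were tested with Fisher's exact test over 50 tested genes on each side and by the rank of that window among all windows of consecutive genes.

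The tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Abcc2, the genes past the threshold in each direction with genes of the lowest p added up to 6, the members of each list past the threshold or else the 2 with the lowest p, and passing genes beside Abcc2. A gene was named by 1 probe set, and no other probe set of a named gene differed in the opposite direction at an unadjusted p under 0.05. Akr1b8, Gstm5, Gsta1, Ranbp17 and the genes beside Abcc2 at an unadjusted p under 0.01 were named after their values were seen.

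The fit was tested on simulated arrays with the means and spreads of the 18625 probe sets of this comparison, of which some were changed. Of 50 probe sets changed 1.5-fold 70.0% were recovered, of 50 changed 2-fold 78.0%, of 50 changed 3-fold 98.0% and of 50 changed 4-fold 100%. There were 14 false calls among 187, and none in data simulated without a change. The simulation drew probe sets independently and so held no structure shared between arrays. Its 187 calls stand against 4 in the real fit, and more calls ease the adjusted threshold. The recovered shares are therefore too high for a comparison with so few calls, in which Gsta3, at 1.91-fold, missed the threshold. The alternatives changed the floor, the filter, the normalization, the variance model and the weights of arrays, added the Gapdh 3′ to 5′ ratio as a covariate and left out each array in turn. Alternatives added after seeing the data used the leading component of the within-genotype variation as a covariate, the 2 array sets as a block (also with the Gapdh ratio beside it) or alone, all arrays but the 3 deficient ones with the lowest Gapdh ratio, and a floor at the deposited minimum. The mixed form of fry was added then too. For the number of calls, 100 splits of the 12 arrays into 6 and 6, the real one included, were drawn of 462.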

Results

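The data set held 12 arrays of renal cortex from male rats, each from a kidney graft in a wild-type recipient. In 6 arrays the graft was wild type, and in 6 it came from a donor deficient in MRP2. MRP2, encoded by Abcc2, is an export pump of the ATP-binding cassette family that carries organic anions, among them conjugates of glutathione and glucuronic acid, across the apical membrane of proximal tubule cells. The series states its subject as the consequences for renal grafts of losing this pump in the kidney alone, and the comparison was therefore MRP2-deficient against wild-type grafts. The values were deposited probe set signals on a linear scale, and 18625 probe sets passed the level filter. Differences are given as log2(deficient) minus log2(wild type) with the standard error (SE) of the limma fit. The number of arrays, 6 per genotype, limited the precision. The sources used here do not say whether the grafts of a genotype came from separate donors, so the p-values measure the spread between these grafts.

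Abcc2 was 6.47-fold lower in the deficient grafts. Its single probe set had a signal of 0.899 ± 0.0746 (SD, n = 6) in wild-type grafts and 0.141 ± 0.0594 (SD, n = 6) in deficient grafts. The wild-type values lay between 0.787 and 0.987 and the deficient values between 0.0387 and 0.213, without overlap. The log2 difference was -2.69 (SE 0.22, 95% confidence interval of the fold 4.72 to 8.88), and the exact two-sided permutation p was 0.00216, the smallest that 6 against 6 arrays can give. In 1 of the 6 deficient arrays the signal was below the floor set on low values. Where the probe set lies relative to the mutation is not given in the sources used here.

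Few other probe sets differed. In limma with Benjamini-Hochberg adjustment 4 probe sets passed an adjusted p of 0.05, and all 4 were lower in deficient grafts. Beside Abcc2 (adjusted p = 8.35e-06) they were Mxi1 and 2 probe sets without a listed gene. Mxi1, which encodes a transcriptional repressor that antagonizes MYC, was 1.93-fold lower (log2 difference -0.94, SE 0.11, adjusted p = 0.00146), with every deficient array below every wild-type array. The other tested probe set that names Mxi1 did not pass the threshold, so the call rests on 1 probe set. It showed no opposite difference at an unadjusted p under 0.05, a check that does not show agreement. Of the unnamed probe sets, 1 was 5.45-fold lower (adjusted p = 1.42e-06) and the other 2.34-fold lower (adjusted p = 0.0213), both without overlap. The call of the latter was lost in 6 of the 12 fits that left out 1 array. In this fit no probe set passed in the direction of higher signal, against 624 that were higher at an unadjusted p under 0.05 and 862 that were lower, where 931 in all would be expected by chance. With a component of the within-genotype variation as a covariate, chosen after seeing the data, 531 probe sets passed, of which 230 were higher, and with the 2 array sets described with the array measures as a block 112 passed, of which 38 were higher. With the Gapdh 3′ to 5′ ratio, described there too, beside that block 3 passed, of which 0 were higher.

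**Figure D1:**
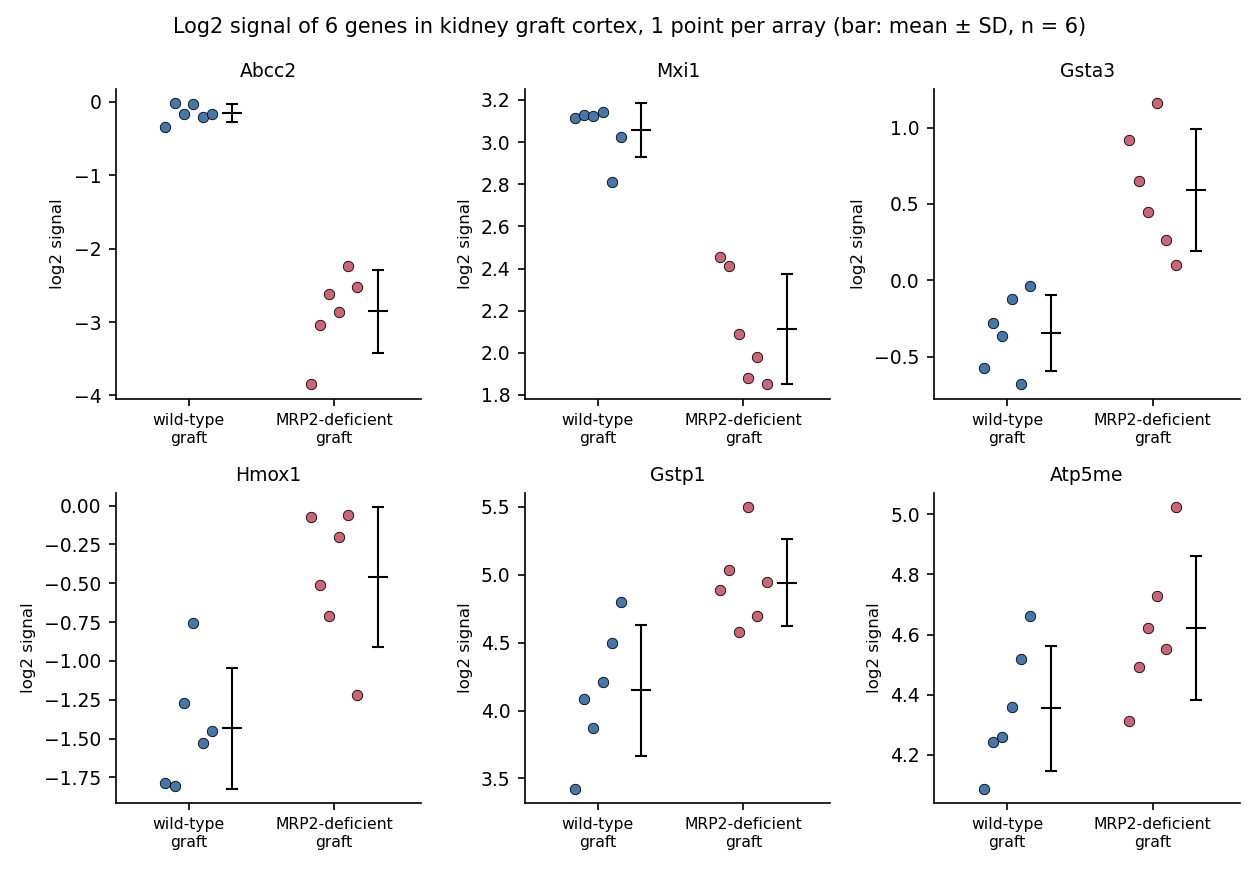
Log2 signal (vertical axis, after the floor) of 6 genes in wild-type and MRP2-deficient grafts, 1 point per array, with the mean and SD of 6 arrays as the bar. Abcc2 and Mxi1 do not overlap between the genotypes, Gsta3 does not overlap either but missed the adjusted threshold, and Hmox1, Gstp1 and Atp5me overlap.

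The genes with the lowest p that were higher in deficient grafts did not pass the threshold over all arrays with equal weights and no covariate, and are given as values. Gsta3, a glutathione S-transferase, had a log2 difference of 0.93 (SE 0.17, adjusted p = 0.161). Hmox1, the inducible heme oxygenase, had 0.97 (SE 0.21, adjusted p = 0.465). Adipor2, an adiponectin receptor, had 0.58, Aadac, an arylacetamide deacetylase, 0.51, Dtna 0.75 and the tropomyosin gene Tpm1 0.60, with adjusted p between 0.273 and 0.560. In each of these 6 genes all 6 deficient arrays lay above the wild-type mean. The choice of these genes by lowest p makes this likely, so it is not separate support. With the component of the within-genotype variation as a covariate all 6 passed, with adjusted p between 0.00814 and 0.0330, and Gsta3 also passed without deficient replicate 14 (adjusted p = 0.0455) and with array weights (adjusted p = 0.0308). Without the level filter the dim gene Ranbp17 passed, with a log2 difference of 1.36 (adjusted p = 0.00666). Its mean log2 signal was -3.04, under the filter cut of -2.53, where values raised to the floor can narrow the spread. Among genes with lower values, Ptpn22, a phosphatase of lymphocytes, had a log2 difference of -1.04 (SE 0.21, adjusted p = 0.381). The values were -0.61 for Sbf1, -0.64 for Ccni and -0.36 for the deubiquitinase gene Usp7, with adjusted p between 0.273 and 0.513. With the component as a covariate these 4 genes passed too, with adjusted p between 0.00652 and 0.0188. The component was taken with the genotype means removed, so it left each difference unchanged and narrowed the spread alone. With it 19 of 100 splits of the arrays, the real one included, gave at least the 531 calls of this fit. These passes are therefore not separate support for the genes named here.

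Genes that the transcription factor NRF2 controls in the antioxidant response were called higher in deficient grafts relative to other genes. The call did not hold in all set tests. Of 29 tested members of this list 22 had a positive and 7 a negative log2 difference, with a median of 0.11 against -0.041 over all genes. The list passed the set test, camera with a preset inter-gene correlation, at an adjusted p of 1.09e-07. With an estimated correlation the call was lost (adjusted p = 0.130), and fry, which tests against no change, gave an adjusted p of 0.166. The mixed form of fry, added after seeing the data, gave an adjusted p of 0.0133. It asks whether members change in either direction and does not bear on whether the list is higher. Over other splits of the 12 arrays into 6 and 6, camera with the preset correlation called a median of 5 lists, against 6 in the real split. No member passed over all probe sets, so 29 of 29 missed that threshold, and 5 members passed adjusted over the list alone. These were Gsta3, Hmox1, Gstp1, the aldo-keto reductase gene Akr1b8 and the epoxide hydrolase gene Ephx1. Gstp1 had a log2 difference of 0.79 (SE 0.19), Akr1b8 0.76 (SE 0.19) and Ephx1 0.28 (SE 0.09). Without Gsta3, Hmox1, Gstp1 and Akr1b8, left out after their values were seen, the median of the other 25 members was 0.086. Camera with the preset correlation then gave an unadjusted p of 1.13e-04. The mean signal of the list per array, relative to all arrays, was 0.0938 ± 0.117 (SD, n = 6) in deficient and -0.0938 ± 0.0804 (SD, n = 6) in wild-type grafts, with an exact permutation p of 0.0130 and 0.156 after adjustment over 24 lists. It was above every wild-type array in 5 of the 6 deficient arrays. In array set 2, the part of the arrays described with the array measures that holds 3 grafts of each genotype, the list had an adjusted p of 0.159.

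Genes of glutathione synthesis, breakdown and conjugation were also called higher relative to other genes, and this call too did not hold in all set tests. Of 34 tested members 28 had a positive and 6 a negative difference, with a median of 0.15, and the list passed at an adjusted p of 2.73e-07. With an estimated correlation the adjusted p was 0.204, and by fry 0.302. With the Gapdh 3′ to 5′ ratio as a covariate the mean log2 difference of the list went from 0.16 to 0.10 (adjusted p = 0.00224 with the preset correlation). None of the 34 members passed over all probe sets, and Gsta3 and Gstp1 passed adjusted over the list alone. Gstm5 had a log2 difference of 0.34 and Gsta1 of 0.26. This list shared 6 tested genes with the NRF2 list, and without them its median was 0.14 and that of the NRF2 list 0.10. Without deficient replicates 3, 10 and 14, which had the lowest Gapdh 3′ to 5′ ratios, the adjusted p of the glutathione list was 0.0710. These are all the deficient arrays of array set 2, so that fit was unbalanced by array set, and in array set 1 alone, which holds none of them, the adjusted p was 2.28e-07.

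Subunits of the mitochondrial respiratory chain passed the set test with small differences, and the call did not hold in all fits. Of 51 tested members 48 had a positive difference and 3 a negative one, with a median of 0.12, and the adjusted p was 9.09e-08. With an estimated correlation of 0.518 between members the adjusted p was 0.663. Atp5me, a subunit of the ATP synthase, had a log2 difference of 0.27 (SE 0.12) and Sdhd, a subunit of succinate dehydrogenase, 0.19 (SE 0.09). No member passed over all probe sets or adjusted over the list alone. With the Gapdh 3′ to 5′ ratio as a covariate the adjusted p was 0.909. Without deficient replicates 3, 10 and 14, a fit unbalanced by array set, the list was lower in deficient grafts (mean log2 difference -0.064, adjusted p = 0.00669). In array set 1 alone it was higher relative to other genes, with a median of 0.035 against -0.051 over all genes (adjusted p = 7.97e-05).

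**Figure D2:**
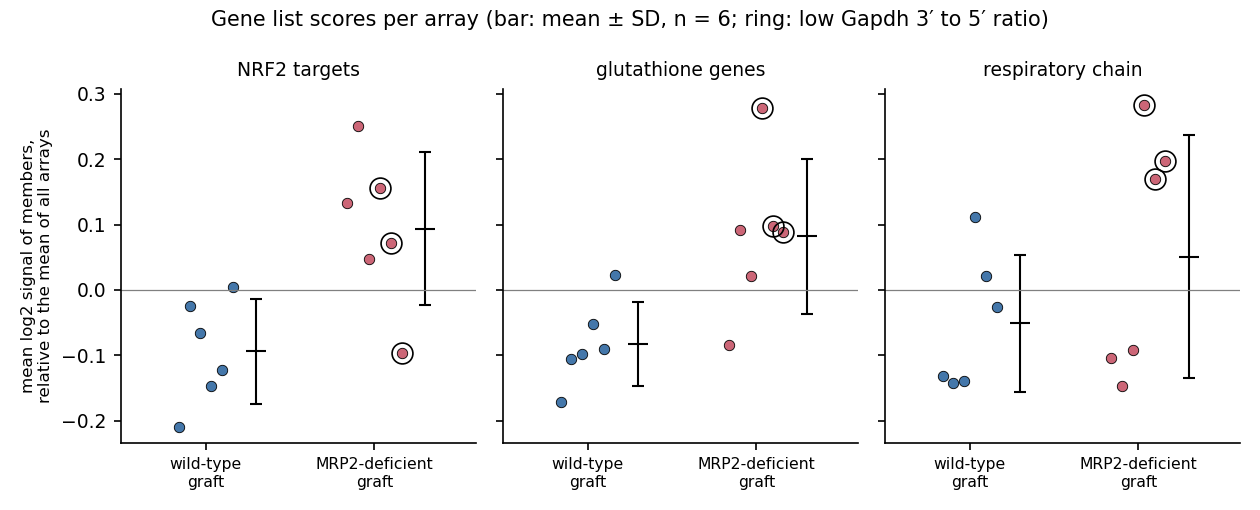
Mean log2 signal of the tested members of 3 gene lists per array (vertical axis, relative to the mean of all arrays), for wild-type and MRP2-deficient grafts, with the mean and SD of 6 arrays as the bar and rings around deficient replicates 3, 10 and 14. In the respiratory chain list the ringed arrays lie above all other arrays, and in the NRF2 list 5 of the 6 deficient arrays lie above every wild-type array.

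A further 3 lists passed with higher adjusted p. Genes of tubular injury and repair had 21 positive and 5 negative differences among 26 tested (median 0.15, adjusted p = 0.00247). With an estimated correlation the adjusted p was 0.663, and it was 0.236 with the Gapdh ratio as a covariate and 0.340 in array set 1 alone. The 2 members with the lowest p went opposite ways. Krt8, a keratin of simple epithelia, had a log2 difference of -0.28 (SE 0.12) and Anxa2, a calcium-dependent phospholipid-binding protein, 0.23 (SE 0.11). Cell cycle genes had 21 positive and 11 negative differences among 32 tested (median 0.12, adjusted p = 0.0123). With an estimated correlation the adjusted p was 0.663, the call was lost in 5 of 12 fits that left out 1 array, and the direction turned when values below 1 were set to 1. The mean signal of the list stood apart from the others of its genotype in wild-type replicate 1 (higher) and deficient replicate 14 (lower). Kif11, a mitotic motor protein, had -0.42 (SE 0.11) and the replication licensing gene Mcm5 0.35 (SE 0.17). Markers of macrophages and other myeloid cells had 18 positive and 9 negative differences among 27 tested (median 0.10, adjusted p = 0.0233, 0.663 with an estimated correlation). That call was lost in 3 of 12 fits that left out 1 array, and the adjusted p was 0.177 with the Gapdh ratio as a covariate. Itgax had -0.34 (SE 0.11) and the mannose receptor gene Mrc1 0.38 (SE 0.15). No member of these 3 lists passed over all probe sets or adjusted over the list alone.

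Other transporters and enzymes of conjugate handling did not pass as groups. Among 12 tested ABC transporters of drugs, bile acids and sterols (adjusted p = 0.772), Abcc4 had a log2 difference of 0.31 (SE 0.12) and Abcc10 of -0.46 (SE 0.23). Abcc10 lay between -0.57 and -0.31 with 1 array left out and between -0.66 and -0.075 in the other alternatives. Among 24 transporters of organic anions and cations of the solute carrier families 19 had a negative difference (adjusted p = 0.181), and the bile acid transporter gene Slc10a2 had -0.37 (SE 0.10) and Slc22a4 -0.29 (SE 0.11). Enzymes of glucuronidation and sulfation (14 tested, adjusted p = 0.619) held Ugt2b7 at 0.61 (SE 0.24) and Sult1c2 at -0.15 (SE 0.07). Cytochrome P450 and other phase I enzymes (31 tested, adjusted p = 0.978) held Ephx1 and Cyp4a8, the second at 0.25 (SE 0.09). In heme, iron and metallothionein genes (21 tested, adjusted p = 0.498) Hmox1 alone passed adjusted over the list alone, and Cpox had -0.29 (SE 0.11). Genes of eicosanoid synthesis and reception (20 tested, adjusted p = 0.561) held Hpgd at -0.60 (SE 0.27) and Ltc4s at 0.30 (SE 0.16). Fatty acid oxidation genes (37 tested, adjusted p = 0.676) held Acox2 at 0.89 (SE 0.26) and Ppargc1a at -0.37 (SE 0.13). Cholesterol synthesis genes (20 tested, adjusted p = 0.772) held Mvd at -0.64 (SE 0.27) and Stard4 at -0.34 (SE 0.12). For the ABC transporter, glucuronidation, eicosanoid and heme lists the median, the mean and the set test, which compares a list with all other genes, differed in sign.

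Markers of nephron segments and of other cell types did not pass either, and no member named here passed over all probe sets. Of 35 proximal tubule markers 25 had a negative difference (adjusted p = 0.181), with Slc5a2, the glucose transporter of the early proximal tubule, at -0.38 (SE 0.11) and Slc26a1 at -0.26 (SE 0.08). Markers of the loop, distal tubule and collecting duct (29 tested, adjusted p = 0.922) held the intercalated cell genes Slc26a4 at -0.42 (SE 0.13) and Slc4a1 at -0.41 (SE 0.12). Glomerulus and endothelium markers (23 tested, adjusted p = 0.498) held Nphs1 at -0.24 and Cd2ap at -0.15. Lymphocyte markers (22 tested, adjusted p = 0.772) held Gzmk at 0.28 and Cd247 at -0.34. Genes of antigen presentation and the interferon response (47 tested, adjusted p = 0.148) held Ifi27 at 0.25 and Cxcl11 at -0.20. Erythrocyte and blood markers (6 tested, adjusted p = 0.220) held the hemoglobin gene Hba-a3 at -0.30 (SE 0.27, -0.078 without deficient replicate 14 and -0.47 without wild-type replicate 1), and Slc4a1 passed adjusted over the list alone. Only 3 markers of fat, muscle, adrenal and liver were above the level filter, too few for a test, and Lpl (-0.085) and Adipoq (-0.074) were among them. With 1 array left out Lpl lay between -0.21 and -0.036 and Adipoq between -0.16 and 0.0038.

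Matrix and stress genes did not pass as groups, though 3 of these lists passed under some alternatives. With an estimated correlation the adjusted p was 0.756 for the matrix list and 0.663 for the endoplasmic reticulum stress and heat shock lists. Extracellular matrix and fibrosis genes (36 tested, adjusted p = 0.0888) held Loxl2 at 0.47 (SE 0.18) and Dcn at 0.36 (SE 0.15), and passed in 5 of 12 fits that left out 1 array. These left out wild-type replicate 1 (adjusted p = 0.0444), 8 (0.0216) or 9 (0.0157) or deficient replicate 9 (0.0119) or 10 (0.00339), and the highest value was 0.667. In the list of endoplasmic reticulum stress and the amino acid response 23 of 31 members had a negative difference (adjusted p = 0.0720), with Sesn2 at -0.25 (SE 0.09) and Dnajb11 at -0.21 (SE 0.09). That list passed, lower in deficient grafts, in 8 of 21 other alternatives and in 2 of 12 fits that left out 1 array (wild-type replicate 8, 0.0273, or deficient replicate 10, 0.0186). In the heat shock list 15 of 22 members had a negative difference (adjusted p = 0.0933), with Hsf1, its main transcription factor, at -0.41 (SE 0.11) and Hspa1a at -0.29 (SE 0.11), and the list passed in 3 of 21 other alternatives and without deficient replicate 10 (adjusted p = 0.0415). Immediate early genes (26 tested, adjusted p = 0.181) held Jund at -0.53 (SE 0.21) and Gadd45a at 0.19 (SE 0.09).

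Genes beside Abcc2 were counted apart, because a mutation carried in another stock brings linked sequence with it. Of the 50 tested genes on each side of Abcc2 on chromosome 1, in the gene order of the GRCr8 assembly, 0 of 100 passed the adjusted threshold, against 1 of 10505 other genes (two-sided Fisher's exact p = 1.00). That other gene was Mxi1, which is itself the tested gene at place 53 from Abcc2. With up to 100 tested genes on each side, 186 in all because one side of the chromosome ends after 86, Mxi1 fell inside and was the sole gene to pass. In limma 8 of the 100 genes had an unadjusted p under 0.01, a measure chosen after seeing the data, against 1.40% of other genes.

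**Figure D3:**
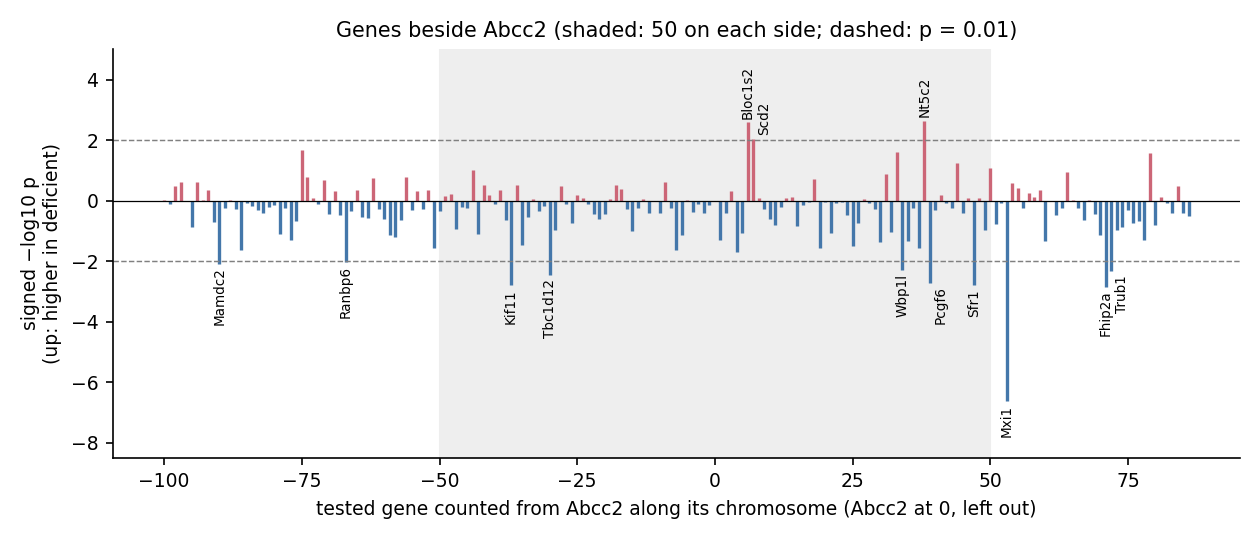
Signed −log10 of the unadjusted limma p (vertical axis, positive where the signal was higher in deficient grafts) of tested genes counted along chromosome 1 from Abcc2 at 0 (horizontal axis), with 50 genes on each side shaded and dashed lines at 0.01. The named genes pass these lines, and Mxi1, at place 53, is the farthest beyond them.

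Several array measures differed with genotype or within it. Control RNAs with poly-A tails, which are added to a sample before labelling, gave higher signals on every deficient array than on every wild-type array in 24 of 24 probe sets. Their mean log2 signal was 0.179 ± 0.181 (SD, n = 6) against -2.49 ± 0.278 (SD, n = 6), with an exact permutation p of 0.00216. The share of probe sets at the floor was 19.2% ± 1.14 (SD, n = 6) in deficient and 20.8% ± 0.670 (SD, n = 6) in wild-type grafts (exact permutation p = 0.0173, 0.0462 after adjustment over 8 measures). The 3′ to 5′ log2 ratio of the Gapdh control probe sets, a sign of RNA quality, was 0.626 ± 0.264 (SD, n = 6) against 0.819 ± 0.0725 (SD, n = 6), with an exact permutation p of 0.132. It lay between 0.359 and 0.449 in deficient replicates 3, 10 and 14 and at or above 0.710 in all other arrays. A lower ratio means more 5′ signal relative to 3′ signal. The same ratio of the Actb control was 2.80 ± 0.442 (SD, n = 6) against 3.05 ± 0.152 (SD, n = 6), with an exact permutation p of 0.232. Deficient replicates 3, 10 and 14 were the lowest in it too, between 2.16 and 2.67, with all other arrays at or above 2.82. They also had the lowest shares at the floor, 17.7% to 18.9%, with all other arrays at or above 19.5%. The median log2 signal of the tested probe sets was -0.0633 against -0.0341 (exact permutation p = 0.394).

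The arrays also fell into 2 sets of 6 that the labels do not name, each with 3 wild-type and 3 deficient grafts. Set 1 held wild-type replicates 1, 6 and 9 and deficient replicates 5, 9 and 11, and set 2 held the remaining arrays. The sets were defined from the data, as opposite signs of the leading component of the within-genotype variation, which held 32.6% of that variation. They match the order in which the samples are listed, where set 1 is the first 3 of each genotype and set 2 the last 3. What this order stands for is not given in the sources used here. Within set 1 the limma fit called 4 probe sets, and within set 2 it called 1190, of which 3 were called in both. Across 18625 probe sets, which are not independent replicates, the log2 differences of the 2 sets had a Pearson r of 0.0572. Abcc2 had a log2 difference of -2.99 in set 1 and -2.40 in set 2, and Mxi1 of -0.80 and -1.09. The median of the NRF2 list was 0.23 in set 1 and 0.091 in set 2, that of the glutathione list 0.14 and 0.16, and that of the respiratory chain list 0.035 and 0.18.

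**Figure D4:**
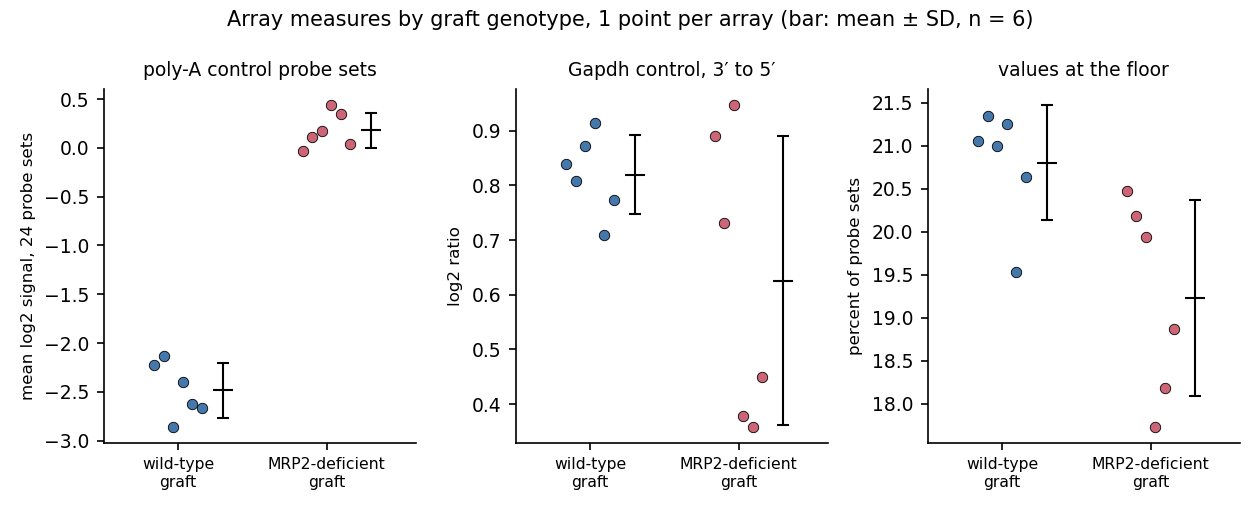
Mean log2 signal of 24 poly-A control probe sets, 3′ to 5′ log2 ratio of the Gapdh control and percent of probe sets at the floor (vertical axes) in wild-type and MRP2-deficient grafts, 1 point per array, with the mean and SD of 6 arrays as the bar. The poly-A controls do not overlap between the genotypes, and 3 deficient arrays have a Gapdh ratio between 0.359 and 0.449.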

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

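The test behind the weighing of the poly-A controls was chosen after the result was seen. The search for outlying arrays covered 134 groups of 6 values (67 measures in each genotype) and found 11, where chance alone gives about 6.7.

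The clearest signal outside the comparison was in the control probe sets for dap, lys, phe and thr, bacterial transcripts with poly-A tails that are added to RNA before labelling. Their median log2 difference between deficient and wild-type grafts was 2.73, a 6.63-fold difference, and in 24 of 24 probe sets every deficient array was above every wild-type array, an order that chance gives a single probe set in 0.108% of assignments. These transcripts do not come from rat tissue, so their signal relative to rat RNA differed between the genotypes for a reason that was not tested. Preparation or labelling apart for each genotype is a candidate source of any difference between the grafts, and it cannot be told apart from the genotype, since all 6 arrays of a genotype share the same state. This limit covers all 4 probe sets called. The labels give the loss of Abcc2 as the graft genotype and do not state its RNA level.

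Single arrays stood apart from the others of their genotype in 11 measures. For Mxi1 wild-type replicate 7 had a log2 signal of 2.81 against 3.03 to 3.14 in the other wild-type grafts, still above every deficient graft. Abcc4 was 2.35 in deficient replicate 5 against at most 1.92 in the others, and Slc22a4 was 1.22 in deficient replicate 9 against at most 0.779. Among wild-type grafts Ephx1 was 3.12 in replicate 1 (others at least 3.43) and Cyp4a8 was 4.80 in replicate 8 (others at most 4.49). Wild-type replicate 4 stood apart in 3 genes, with Slc26a1 at 3.71 (others at most 3.48), Gadd45a at 2.44 (others at least 2.69) and Lpl at 0.729 (others at least 1.33). The median log2 signal of deficient replicate 14 was -0.167 against at least -0.0761 in the other deficient arrays. The cell cycle score was 0.349 in wild-type replicate 1 against at most 0.00967 in the other wild-type grafts, and -0.262 in deficient replicate 14 against at least 0.0233 in the other deficient grafts.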

How the results depend on the processing

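Settings named here as added were chosen after seeing the data. No paired analysis was possible because the 2 genotypes share a single replicate number, 9. The log2 difference of Abcc2 kept its direction and stayed past the threshold in all 27 alternatives that gave one, between -3.01 and -2.22. With values below 1 set to 1 it had no value, since all its signals are below 1, and the 60th percentile filter removed it. Mxi1 and the unnamed probe set with the larger fold passed in all 29 alternatives each, and the other unnamed probe set in 15 of 28. The number of probe sets past the threshold was between 3 and 5 when 1 array was left out. It was 2 with values below 1 set to 1 and 2 with a filter at the 60th percentile, where fewer of the 4 probe sets were tested. Of the added settings, the leading residual component as a covariate gave 531, array set as a block 112, this block beside the Gapdh ratio 3, array set 2 alone 1190 and omission of the 3 arrays of lowest Gapdh ratio 3.

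The number of gene lists past the threshold was 0 with an estimated correlation, 0 by fry (1 in its mixed form, added), 3 with the Gapdh ratio as a covariate and 10 with quantile normalization (6 higher, 4 lower), and 4 to 8 with 1 array left out. By fry the adjusted p was 0.166 for NRF2 targets, 0.302 for glutathione, 0.602 for injury, 0.654 for macrophages, 0.654 for the respiratory chain and 0.664 for the cell cycle. With an estimated correlation it was 0.130 for NRF2 targets, 0.204 for glutathione and 0.663 for the respiratory chain, injury, cell cycle and macrophage lists. With the Gapdh ratio as a covariate it was 0.236 for injury, 0.177 for macrophages and 0.909 for the respiratory chain. Without the 3 deficient arrays of lowest Gapdh ratio (added) it was 0.0710 for glutathione, 0.955 for injury and 0.900 for macrophages, and the respiratory chain list reversed at 0.00669. That fit is unbalanced, since these are all the deficient arrays of array set 2. With array set as a block beside the Gapdh ratio (added) all 6 lists passed. The cell cycle list reversed, not past the threshold, when values below 1 were set to 1 (0.840), and had 0.719 with the 60th percentile filter, where the macrophage list had 0.0674, and 0.142 with quantile normalization. In array set 1 alone (added) the adjusted p was 0.340 for injury, 0.105 for macrophages and 0.0531 for the cell cycle. In array set 2 alone (added) it was 0.159 for NRF2 targets, 0.0957 for macrophages and 0.314 for the cell cycle. With 1 array left out it ranged from 0.00130 to 0.183 for macrophages and from 2.88e-06 to 0.0966 for the cell cycle. The macrophage call was lost without wild-type replicate 6 (0.183) and without deficient replicates 11 (0.138) and 10 (0.0575). That of the cell cycle was lost without wild-type replicates 6 (0.0966), 9 (0.0571) and 7 (0.0544) and deficient replicates 9 (0.0534) and 11 (0.0765). The causes were not tested.

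The count of passing genes beside Abcc2, 0 of 100, was 0 in each fit without 1 array. It was 1 with up to 100 genes on each side, with values below 1 set to 1 and with the 60th percentile filter, since Mxi1 then falls inside. It was 10 with the residual component, 5 with the array set block and 9 in array set 2 alone (all added). The difference in the Gapdh ratio lay between -0.258 and -0.140 with 1 array left out, and without deficient replicate 11 (-0.258) its exact permutation p was 0.0433. Of 1596 values of the other 56 named genes under alternatives, none turned with a call and 51 came past the threshold. Of 593 values of the 18 lists that did not pass, 32 came past it, in 7 lists. With 1 array left out the antigen presentation list passed without wild-type replicate 4 (0.0151) and deficient replicates 3 (0.0326) and 9 (0.0151), and the organic anion and cation transporter list without deficient replicate 9 (0.0360). In the other alternatives the endoplasmic reticulum stress list passed in 8, heat shock and antigen presentation in 3 each, the proximal tubule and organic anion and cation transporter lists in 2 each, and the matrix and lymphocyte lists in 1 each. Signals near the floor limit what dim probe sets can show, since 17.7% to 21.3% of the values of an array lie at or below it.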

Other observations

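The tests of explanations below, the count of genes beside Abcc2 over other splits of the arrays and all counts over splits balanced by array set were chosen after the results were seen, while the other counts over splits were set before their result was known.

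Of the 100 tested genes within 50 places 8 had an unadjusted p under 0.01, of which 5 were lower and 3 higher in deficient grafts. The lower ones were Kif11 (-0.42 on the log2 scale), Tbc1d12 (-0.38), Wbp1l (-0.26), Pcgf6 (-0.63) and Sfr1 (-0.34). The higher ones were Bloc1s2 (0.37), the desaturase gene Scd2 (1.04) and Nt5c2 (0.44). Bloc1s2 and Scd2 are the tested genes at places 6 and 7 from Abcc2. Beyond the window, Mxi1 at place 53, Fhip2a at place 71 (-0.47) and Trub1 at place 72 (-0.48) were also lower, as were Ranbp6 (-0.55) and Mamdc2 (-0.58) on the other side, at places -67 and -90. Kif11 was the cell cycle gene with the lowest p, and it went against the direction of its list.

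The share of genes with an unadjusted p under 0.01 was 8.00% in the window of 50 genes on each side against 1.40% elsewhere (odds ratio 6.12, two-sided Fisher's exact p = 1.04e-04, genes not being independent), and 40 of 8524 windows of as many consecutive genes held as many. With 25 genes on each side it was 2 of 50 (odds ratio 2.83, Fisher's exact p = 0.166), and with up to 100 on each side 13 of 186 (odds ratio 5.44, Fisher's exact p = 3.17e-06). With the array set as a block it was 2.26, with the residual component 2.04 and with the block and the Gapdh ratio 2.04 (Fisher's exact p = 0.0934), since more genes elsewhere then differed. Leaving out 1 array moved it from 3.76 (without deficient replicate 11) and 3.93 (wild-type 8) to 9.23 (wild-type 1), 9.33 (deficient 10) and 10.2 (deficient 3). Within array set 1 alone the odds ratio was 1.92 (Fisher's exact p = 0.107) and within set 2 alone 1.44 (Fisher's exact p = 0.209), so the excess was not shown within either set. A candidate explanation is sequence of the donor stock linked to the mutation. Base differences under the probes in place of differences in RNA cannot be told apart from it, because 5 of 8 genes were lower and the stock behind the array sequence is not known here.

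Other splits of the arrays did not settle whether chance can be excluded for the genes beside Abcc2. For the odds ratio it cannot, since 10 of 100 splits of the arrays gave one as high (6.45 with 0.5 added to each count, against 16.1 in the highest other split). The other splits reached it with 1 or 2 genes in the window. For the count of 8 genes 3 of 100 splits gave as many, with 11 in the highest other split. Both other splits put 10 of 12 arrays with their array set. This count was chosen after the results were seen and rises with the number of genes at that p anywhere, so it does not exclude chance. It was 4 with the Gapdh ratio as a covariate and between 6 and 12 with 1 array left out. Of the 51 splits drawn that, like the real one, were balanced by array set, 7 gave as high an odds ratio and the highest other count was 2.

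The higher signal of the NRF2 and glutathione lists was weighed against RNA quality and preparation. With the Gapdh ratio as a covariate the mean log2 difference of the NRF2 list was 0.20 (SE between arrays 0.069) against 0.19 without it, with the array set as a block beside the ratio it was 0.18 (SE 0.080), and in array set 1 alone 0.24 (SE 0.081). For the glutathione list the mean went from 0.16 to 0.10 (SE 0.050, adjusted p = 0.00224), and was 0.13 (SE 0.055) with the array set beside the ratio and 0.13 (SE 0.056) in array set 1 alone. Both lists stayed past the threshold with the preset correlation in these fits, but that test also called lists in other splits of the arrays. The mean of the NRF2 list stayed between 0.18 and 0.24, which argues against this ratio as its whole cause. Part of the glutathione difference may go with the ratio. Without the 3 deficient arrays of lowest ratio, a fit unbalanced by array set, the adjusted p of the set test was 0.0710 for glutathione and 4.01e-10 for NRF2. Preparation of the RNA apart for each genotype, which 24 of 24 poly-A control probe sets bear on, cannot be told apart from an effect of the graft genotype, since the 2 coincide on every array, and both stay open.

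For the respiratory chain list the fits disagreed, and RNA quality as its cause cannot be told apart. With the Gapdh ratio as a covariate its mean log2 difference went from 0.10 to -0.013 (SD over members 0.069 and 0.056, adjusted p = 0.909), near the mean of all genes, -0.011, which ended the call. With the array set as a block beside the ratio the mean was 0.068 (SE between arrays 0.046, adjusted p = 6.27e-11). In array set 1 alone, which holds none of the 3 arrays of low ratio, it was 0.023 (SE 0.017), against -0.044 over all genes (adjusted p = 7.97e-05). The low ratios are those of all deficient arrays of array set 2, which keeps the ratio, those 3 arrays and a difference in tissue state of those grafts open.

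Over 100 splits of the 12 arrays into 6 and 6, the real one included, 2 gave at least the real count of 4 probe sets. The other such split gave 675 and put 10 of 12 arrays with their array set, which points to a structure of the arrays apart from genotype. The 4 probe sets of the real split include Abcc2, which the labels state is lost, and Mxi1, at place 53 from it. Their count therefore does not exclude chance for genes away from the mutation. For the number of gene lists chance cannot be excluded, since 38 splits gave 6 or more and the highest other gave 12. With the residual component as a covariate, recomputed for each split, 19 splits gave at least the 531 probe sets of the real one, with 4267 in the highest other, so chance cannot be excluded over all splits. All 18 others were unbalanced by array set. Among the 51 splits drawn that were balanced by array set the real one alone, 1 of 51, gave as many, with 212 in the highest other. The array sets were defined with the genotype means removed, which by itself favours the real split, so no count over balanced splits excludes chance. For the number of gene lists 18 of the 51 gave 6 or more.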
